A study of Homo sapiens with 12 samples.

How the data were processed

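The analysis used the gene counts that the authors deposited, with 60675 genes per table. Each group has more count columns than samples, because the columns carry lane labels; lane 1 of each library was used, so 24 of the 36 count columns were not used. The columns carry no replicate number and are called S1 to S12 here by the library number in their names; the group of each comes from the description that the 3 samples of a group share, and which sample each column is stays open. The knockdown columns also carry the word BLANCO, which no source used here explains. Per the submitters' processing notes the tools named upstream are FastQC 0.11.9, MultiQC 1.11, Trimmomatic 0.39, HISAT2 2.1.0, SAMtools and featureCounts 2.0.0 with the genome GRCh38. Their parameters, the annotation release and the strand setting of the counting are not given in the sources used here. The labels describe 48 h of transfection, TRIzol extraction and a stranded TruSeq mRNA kit with paired reads of 76 bp.

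Of the 60675 gene ids, 60356 matched a reference table of gene names. Symbols and types came with the deposited counts. Coordinates and transcript sequences came from the GENCODE v29 annotation (GRCh38). Library totals ran from 6026376 to 10160040 counts, detected genes from 20265 to 23915, and the 10 most abundant genes held 6.44% to 9.88% of the counts. S4 correlated across 12724 genes with the controls S1 to S3 at r = 0.9838, 0.9866 and 0.9931, and with S5 and S6 at 0.9573 and 0.9508, while S5 and S6 had 0.9924. Within the HCC1187 groups r ran from 0.9862 to 0.9941. The biological coefficient of variation was 0.161 in MDA-MB-468, 0.078 there without S4 and 0.081 in HCC1187. All 12 libraries were kept in the analysis as planned. No pair of libraries was a copy of another; the closest pair, S1 and S2, had a chi-square of 1.96 per degree of freedom.

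Each line was fitted by itself with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr (minimum count 10, minimum total 15) and TMM scaling. The difference between the lines was the interaction of line and knockdown over 12 libraries, with the spread of each gene estimated over both lines together. A gene passed at a Benjamini-Hochberg p under 0.05. Standard errors were worked out from the log2 fold change and the F statistic. Gene lists, 41 in number, were written before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01, with at least 5 genes each; every list was tested again with the correlation estimated and with fry. Shared genes were those passing in both lines in the same direction, with an expected number of n1 × n2 / N. Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE or library-total scaling, no filter or CPM 1 in at least 3 libraries, p under 0.01, an absolute log2 fold change of 1, all 12 libraries together, and leaving out each library. A further 5 alternatives were added after the data were seen. CPM levels use library totals scaled by TMM, except that the tests on S4 and the sums of gene classes use plain library totals. Counts and totals are those of lane 1 throughout.

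SOX9-AS1 and SOX9 were always named. Further named genes were the 8 largest rises and 8 largest falls of a line among genes that passed, had an average log2 CPM of at least 1, had control and knockdown libraries that did not overlap, and had a symbol that is not a clone or small-RNA name. Up to 4 members of each described list by smallest p could be named, which of them to print being picked after the values were seen, and so could 6 genes per direction of the difference between the lines and 6 shared genes per direction. Not every gene that meets the rule is reported here. For MDA-MB-468 the rule was applied to the fit without S4 after the values were seen.

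Simulated changes were put into counts drawn to match these libraries, with the noise of each gene drawn independently. They were planted alike in all knockdown libraries of a line, and only in genes above a minimum count. In HCC1187 65.7% of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold changes were recovered, with 7 false calls among 181. In MDA-MB-468 it was 14.9%, 70.1% and 100%, with 13 false among 136, and for the difference between the lines 90% of 4-fold changes. These rates therefore do not apply to genes of few counts, nor where a library departs over many genes together, as S4 did. Intervals printed for single counts cover counting error only. Words of 7 bases were counted in 3′ UTRs taken from the annotation and its transcript sequences. Splits of the libraries into false groups numbered 10 for each line and 100 drawn ones for the difference and the overlap. Left out were the other lanes and levels of sex-linked genes, and nothing was done from raw reads.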

Results

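SOX9-AS1 is a long non-coding RNA gene on the minus strand of chromosome 17 (GRCh38, 72034107 to 72237203), and its span holds the whole of SOX9 on the plus strand. The question was which genes change when SOX9-AS1 is targeted by shRNA in 2 triple-negative breast cancer lines, MDA-MB-468 and HCC1187, each against sh-LacZ controls. Every group has 3 libraries, named S1 to S12 in the order MDA-MB-468 control, MDA-MB-468 knockdown, HCC1187 control, HCC1187 knockdown. A value after ± is an SD for counts scaled to a common library size (CPM) and a standard error for a log2 fold change, and p-values, those of lists included, are adjusted unless said otherwise. The p-values of single genes measure only the spread between these libraries, because nothing in the labels says that the libraries of a group came from separate cultures. List p-values at the preset correlation compare a list with the other genes and take genes as almost independent. Those of the overlap and of the words take genes as the unit, so none of these measures the spread between libraries alone.

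In HCC1187, SOX9-AS1 stood at 2.59, 1.56 and 1.95 CPM in S7 to S9 and at 1.25, 0.765 and 0.868 CPM in S10 to S12. It fell 2.11-fold (log2 fold change −1.08 ± 0.36, adjusted p = 0.0349, n = 3 per group). In MDA-MB-468 it stood at 5.5, 6.62 and 5.93 CPM in S1 to S3 and at 5.01, 4.55 and 5.07 CPM in S4 to S6, with a log2 fold change of −0.30 ± 0.20 that did not pass (adjusted p = 0.417). The MDA-MB-468 values below therefore compare shRNAs without a passing fall of the target. SOX9, which encodes a transcription factor of progenitor and stem-like epithelial cells, fell in HCC1187 from 17.1 ± 1.4 to 12.2 ± 2.31 CPM (log2 fold change −0.49 ± 0.16, adjusted p = 0.0256, n = 3 per group). SOX9 in MDA-MB-468 averaged 186 ± 22.8 CPM in the controls and stood at 135, 109 and 102 CPM in S4, S5 and S6 (log2 fold change −0.68 ± 0.15, adjusted p = 0.205 with all 6 libraries; −0.82 ± 0.10, adjusted p = 2.03e-05 without S4). The fall of SOX9-AS1 in HCC1187 rests on 5 to 24 counts per library, from the 1 of 3 lanes used here, and is lost without S7 (adjusted p = 0.168), S9 (0.07), S11 (0.0891) or S12 (0.136), and that of SOX9 without S8 (0.0992), S9 (0.0714) or S12 (0.204). SOX9 in HCC1187 also does not pass with DESeq2 (0.0514) or with all 12 libraries fitted together (0.0919). With S4 kept, SOX9 in MDA-MB-468 did not pass in the main fit. It passed with DESeq2 (adjusted p = 0.013), with all 12 libraries fitted together (0.0221) and with no filter on low counts (0.000107). These fits use the same MDA-MB-468 libraries and differ in how the spread is estimated, so they are not separate support. SOX9 and SOX9-AS1 overlap on opposite strands and the strand setting of the counting is not given in the sources used here, so neither value is certain to belong to its gene alone.

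**Figure D1:**
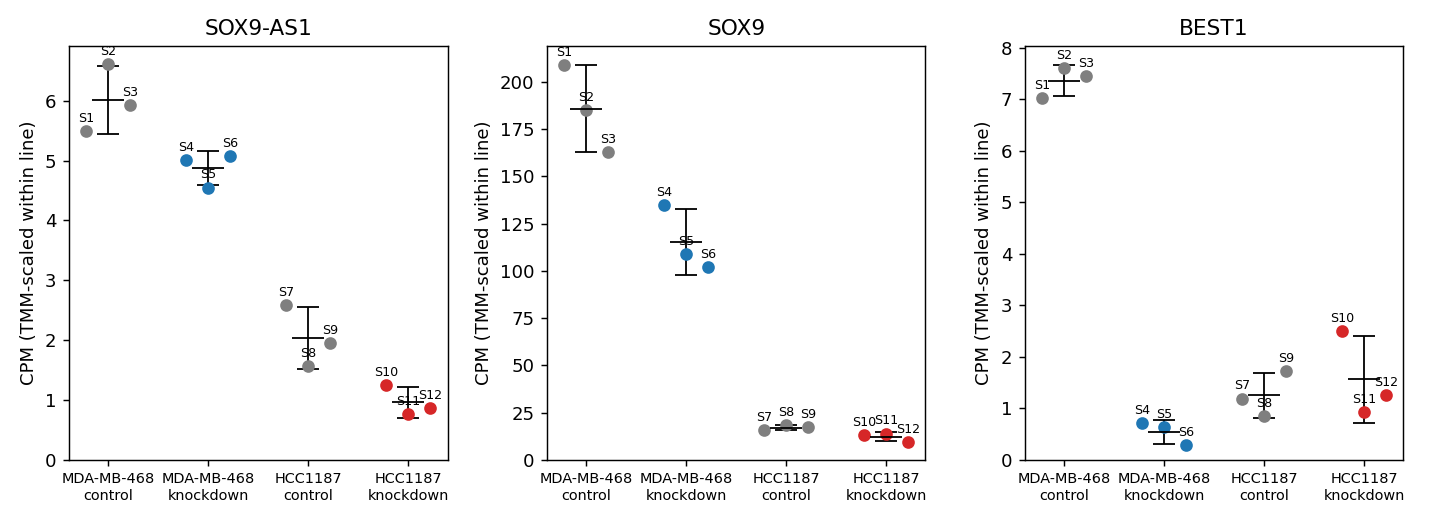
CPM of SOX9-AS1, SOX9 and BEST1 in each library, with the mean and SD of each group of 3. The mean of SOX9-AS1 is 2.03 CPM in the HCC1187 controls and 0.962 CPM in the HCC1187 knockdown.

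Knockdown in HCC1187 lowered CCN2 most among the named genes, 4.73-fold from 14.9 ± 0.911 to 3.04 ± 0.395 CPM (log2 fold change −2.24 ± 0.19, adjusted p = 1.79e-08, n = 3 per group). CCN2 encodes a secreted matrix protein and is a well-known target of YAP and TAZ. PCK1, an enzyme of gluconeogenesis, fell from 80.9 ± 35.3 to 21.6 ± 9.16 CPM (log2 fold change −1.88 ± 0.24), and SCD5, a fatty acid desaturase, fell by 1.69 ± 0.12 on the log2 scale. TMEM263 fell from 141 ± 19.6 to 39.7 ± 7.52 CPM (−1.81 ± 0.12, adjusted p = 7.51e-10), and EXTL3, a glycosyltransferase of heparan sulfate synthesis, fell by 1.56 ± 0.10. PKIB (−1.72 ± 0.17), TAF13 (−1.48 ± 0.15) and MYADM (−1.48 ± 0.14) complete the 8 largest named falls. The largest named rises were THBS4 (2.07 ± 0.31, from 0.944 ± 0.212 to 3.88 ± 0.705 CPM), WDR31 (1.93 ± 0.24), RDM1P5 (1.91 ± 0.28), PSMG3-AS1 (1.81 ± 0.27), TXLNB (1.79 ± 0.34), FAM86C2P (1.71 ± 0.25) and DNAH6 (1.65 ± 0.26). Across the 14970 genes tested, 1464 rose and 1954 fell, and the change was at least 2-fold for 195 and 132 of them. Of the fits that leave a library out, the count is smallest without S8 (2213 genes, 862 up and 1351 down), and with all 12 libraries fitted together it is 1499, which keeps 43.6% of the calls. With library totals as the only scaling 57.7% of the calls are rises against 42.8% with TMM scaling.

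**Figure D2:**
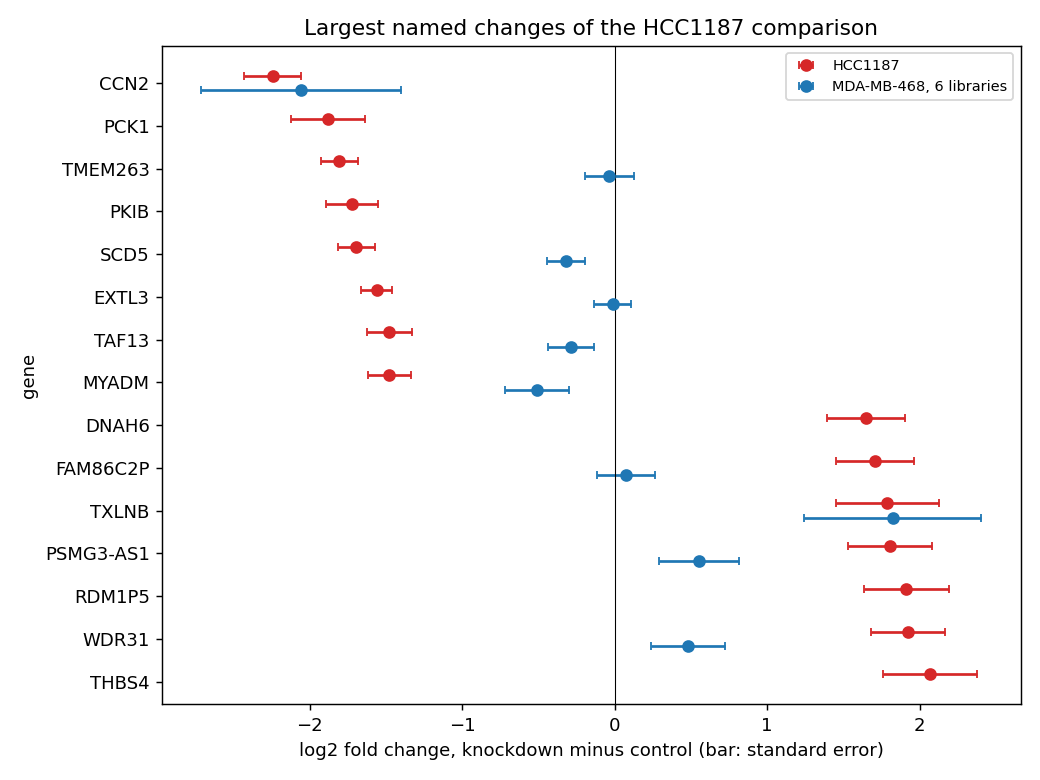
Log2 fold change and standard error of the largest named rises and falls of the HCC1187 comparison, with the MDA-MB-468 value where the gene was tested there. CCN2 has −2.24 in HCC1187 and THBS4 has 2.07.

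Target genes of Notch, TGF-beta and Hippo signalling moved down in HCC1187: 12 of 19 fell, 0 rose and 7 did not pass (13 down adjusted over the list alone). The shift of these targets had list p = 4.49e-07, and adjusted p = 0.179 with an estimated correlation. Besides CCN2, AMOTL2, another gene of the YAP response, fell by 0.77 ± 0.12 on the log2 scale. Of the 23 EGFR, MAPK and immediate-early genes 14 fell, 0 rose and 9 did not pass (14 adjusted over the list alone). Their shift had list p = 1.89e-06, and adjusted p = 0.463 with an estimated correlation. The immediate-early genes FOS (−1.26 ± 0.19) and JUN (−0.39 ± 0.09) and the MAPK phosphatase gene DUSP1 (−1.03 ± 0.11) were among them. Of the 25 genes of the actin cytoskeleton and cell migration 10 fell, 0 rose and 15 did not pass (12 down and 1 up adjusted over the list alone). Cytoskeleton genes as a list had p = 0.00526, and adjusted p = 0.463 with an estimated correlation. EZR, which links actin to the membrane, fell by 0.97 ± 0.09, and RAC1, a GTPase of cell protrusion, fell by 0.52 ± 0.09.

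Glycolysis, hypoxia and cholesterol synthesis genes moved down in HCC1187 and fatty acid oxidation moved up, though none of these lists passes with an estimated correlation. LDHA, which makes lactate, fell from 2050 ± 147 to 1190 ± 194 CPM (log2 fold change −0.76 ± 0.10, adjusted p = 1.37e-05). With LDHA, 7 of the 23 glycolysis genes fell, 0 rose and 16 did not pass (7 adjusted over the list alone). Glycolysis as a list had p = 0.00598, and adjusted p = 0.463 with an estimated correlation. Of 18 hypoxia genes 8 fell, 0 rose and 10 did not pass (11 down adjusted over the list alone). P4HA1 (−0.89 ± 0.12) and NDRG1 (−0.72 ± 0.10) were among them (list p = 6.09e-05, adjusted p = 0.463 with an estimated correlation). Fatty acid oxidation had 8 of 25 genes up, 1 down and 16 not passing (8 and 1 adjusted over the list alone). Its list p was 0.00911, and adjusted p = 0.288 with an estimated correlation. CPT2, of fatty acid import into mitochondria, rose by 0.71 ± 0.10, and ECHS1, of beta-oxidation, by 0.69 ± 0.09. Of 24 cholesterol synthesis genes 8 fell, 3 rose and 13 did not pass (8 and 3 adjusted over the list alone). Cholesterol synthesis as a list had p = 0.0353, and adjusted p = 0.463 with an estimated correlation. HMGCS1 (−0.64 ± 0.11) and SQLE (−0.60 ± 0.10) fell. Neither passes when all 12 libraries are fitted together, and neither do AMOTL2 and JUN above. Oxidative phosphorylation did not shift as a list, with 6 of 35 genes up, 3 down and 26 not passing (7 and 3 adjusted over the list alone; list p = 0.107, adjusted p = 0.624 with an estimated correlation). Nor did the TCA cycle, with 3 of 22 up, 0 down and 19 not passing (0 adjusted over the list alone; list p = 0.597, adjusted p = 0.795 with an estimated correlation).

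Among the other lists of HCC1187, MHC class I and antigen presentation moved up, with 5 of 15 genes up, 0 down and 10 not passing (5 adjusted over the list alone). ERAP1, which trims peptides, rose by 0.53 ± 0.11 (list p = 0.00986, adjusted p = 0.288 with an estimated correlation). LIN28B, an RNA-binding protein that blocks let-7 processing, fell from 154 to 65.1 CPM (−1.22 ± 0.10) and the neurofilament gene NEFM from 244 to 119 CPM (−1.01 ± 0.10). Both are in a list of HEK293-line markers, of which 4 of 6 fell, 0 rose and 2 did not pass (4 adjusted over the list alone). HEK293-line markers had list p = 0.00169, and adjusted p = 0.288 with an estimated correlation. Histone genes moved down, with 6 of 11 down, 0 up and 5 not passing (7 adjusted over the list alone). H1-2 fell by 0.75 ± 0.12, and the histone list had list p = 0.0109, and adjusted p = 0.463 with an estimated correlation. The matrix list had 5 of 21 down, 2 up and 14 not passing (9 and 2 adjusted over the list alone; list p = 0.0109, adjusted p = 0.463 with an estimated correlation). ADAMTS1, a secreted protease, fell from 601 to 256 CPM (−1.204 ± 0.12). In the list of pentose phosphate genes and NRF2 targets 5 of 15 fell, 1 rose and 9 did not pass (6 and 1 adjusted over the list alone; list p = 0.0204, adjusted p = 0.463 with an estimated correlation). HMOX1, the haem-degrading enzyme, fell by 1.16 ± 0.12. In the list of Wnt targets and stem cell genes 7 of 18 fell, 1 rose and 10 did not pass (7 and 1 adjusted over the list alone; list p = 0.0247, adjusted p = 0.463 with an estimated correlation). The transcription factor gene SOX4 fell by 1.096 ± 0.10.

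Of the remaining 4 shifted lists of HCC1187, the list of serine synthesis and the amino acid ATF4 response had 7 of 19 genes down, 1 up and 11 not passing (7 and 1 adjusted over the list alone; list p = 0.0109, adjusted p = 0.463 with an estimated correlation). In the integrin and adhesion list 6 of 21 fell, 1 rose and 14 did not pass (7 and 1 adjusted over the list alone; list p = 0.0247, adjusted p = 0.463 with an estimated correlation). The short-lived and intron-rich nuclear RNAs had 3 of 11 down, 0 up and 8 not passing (3 adjusted over the list alone; list p = 0.0438, adjusted p = 0.463 with an estimated correlation). GAS5, a snoRNA host gene, fell by 0.56 ± 0.10. Ribosomal protein genes had 1 of 34 up, 0 down and 33 not passing (1 adjusted over the list alone; list p = 0.03, adjusted p = 0.711 with an estimated correlation). Altogether 17 of 38 lists shifted, 3 up and 14 down, but 0 did with an estimated correlation and 11 did without S9.

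In MDA-MB-468, BEST1 fell 13.1-fold, from 7.03, 7.62 and 7.45 CPM in the controls to 0.716, 0.631 and 0.282 CPM in S4, S5 and S6 (log2 fold change −3.71 ± 0.32, adjusted p = 0.0248, n = 3 per group). BEST1 encodes a calcium-activated chloride channel. It overlaps FTH1 on the opposite strand, so with an unstated strand setting its reads are not certain to be its own. It was the only gene of 13638 to pass in edgeR with all 6 libraries (0 up, 1 down), and the call is lost when any library except S4 is left out (adjusted p = 0.253 without S1, 0.303 without S2, 0.251 without S3, 0.307 without S5, 0.104 without S6). Its log2 fold change stayed between −3.84 and −3.41 in those fits. At unadjusted p under 0.05 there were 2554 genes, and DESeq2 called 289 (214 up, 75 down) and limma-voom 0. With S4 kept, edgeR called 1441 genes (876 up, 565 down) with no filter on low counts and 887 (604 up, 283 down) with all 12 libraries fitted together. Without S4 it called 5676 genes of 13947 (40.7%, 2791 up and 2885 down). The target SOX9-AS1 did not pass in that fit either (log2 fold change −0.32, adjusted p = 0.274). S4 is missing from the sample table that lists the other 11 libraries, and a fit without each library was fixed before the data were examined. Values without S4 (n = 3 controls, 2 knockdown libraries) therefore follow, with the value of S4 beside only some of them. The choice to describe that fit, and to name genes from it, was made after the values were seen.

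Without S4, SCD, the stearoyl-CoA desaturase, rose from 167 ± 12.8 CPM in the controls to 2500 and 2630 in S5 and S6, with 188 in S4 (log2 fold change 3.94 ± 0.09, adjusted p = 9.45e-14). INSIG1, a sterol-regulated brake on SREBP, rose by 3.85 ± 0.22, STAC2 by 4.19 ± 0.16, PNPLA3, a lipid droplet protein, by 3.79 ± 0.21, C6orf223 by 3.74 ± 0.11, CYP4F23P by 3.39 ± 0.18 and LINC02615 by 3.20 ± 0.22. The largest named falls were PLA2G2A (−6.03 ± 0.33), a secreted phospholipase, CALHM5 (−5.75 ± 0.66, with no read in S5), INHBA (−5.53 ± 0.25), CYP1A1 (−5.16 ± 0.37), FYB1 (−4.72 ± 0.39), KRT79 (−4.28 ± 0.60), THBS1 (−3.99 ± 0.23) and FLG-AS1 (−3.94 ± 0.53). In S4, PLA2G2A stood at 67.8 CPM, INHBA at 26.1 and THBS1 at 126, against control means of 49, 40.6 and 222 CPM. With all 6 libraries SCD had 3.41 ± 0.78 on the log2 scale and did not pass in edgeR. It passed with DESeq2 (adjusted p = 0.0288), with all 12 libraries fitted together (0.0221) and with no filter on low counts (2.08e-41). These fits use the same MDA-MB-468 libraries and differ in how the spread is estimated, so they are not separate support. With 188 CPM in S4 against 2500 and 2630 in S5 and S6, the p-value of 2.08e-41 does not reflect the spread of the knockdown libraries.

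Of 25 cholesterol synthesis genes, without S4 24 rose, 0 fell and 1 did not pass (24 adjusted over the list alone; list p = 1.63e-24, adjusted p = 0.372 with an estimated correlation). MVD rose by 2.75 ± 0.09 and FDPS by 2.01 ± 0.07, both enzymes of the mevalonate pathway. With all 6 libraries 0 of the 25 passed and 23 were up adjusted over the list alone, with a median log2 fold change of 1.70 (list p = 7.43e-08, adjusted p = 0.452 with an estimated correlation). The median of the list against the controls was −0.16 in S4, 2.16 in S5 and 2.24 in S6. Of 27 fatty acid and triglyceride synthesis genes 15 rose, 5 fell and 7 did not pass without S4 (15 and 5 adjusted over the list alone; list p = 0.00012, adjusted p = 0.346 with an estimated correlation). FASN, the fatty acid synthase, rose by 2.27 ± 0.09 (from 423 to 2270 and 1830 CPM, S4 458) and ACLY by 1.43 ± 0.07. In the same fit 15 of 27 interferon genes rose, 2 fell and 10 did not pass (17 and 3 adjusted over the list alone; list p = 0.00165, adjusted p = 0.377 with an estimated correlation). IRF7, an interferon regulator, rose by 1.37 ± 0.18. Of 19 genes of serine synthesis and the amino acid ATF4 response 11 rose, 4 fell and 4 did not pass (13 and 4 adjusted over the list alone; list p = 0.0159, adjusted p = 0.598 with an estimated correlation). DDIT4, an inhibitor of mTORC1, rose by 3.07 ± 0.16. The mitochondrially encoded list had 7 of 13 up, 1 down and 5 not passing (8 and 1 adjusted over the list alone; list p = 0.00633, adjusted p = 0.61 with an estimated correlation). MT-CO3, of complex IV, rose by 0.995 ± 0.09.

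Basal breast markers in MDA-MB-468 moved down without S4: 9 of 16 fell, 2 rose and 5 did not pass (10 and 2 adjusted over the list alone; list p = 0.000266, adjusted p = 0.346 with an estimated correlation). KRT17 fell by 2.46 ± 0.11, from 563 to 112 and 92.1 CPM with 573 in S4, and KRT5 by 1.02 ± 0.08. Of 19 Notch, TGF-beta and Hippo genes 13 fell, 0 rose and 6 did not pass (13 adjusted over the list alone; list p = 2.34e-06, adjusted p = 0.372 with an estimated correlation). CCN2 fell by 3.66 ± 0.34 and AMOTL2 by 1.12 ± 0.09. Of 17 Wnt target and stem cell genes 12 fell, 3 rose and 2 did not pass (12 and 3 adjusted over the list alone; list p = 0.000391, adjusted p = 0.372 with an estimated correlation). MYC fell by 1.77 ± 0.10 from 214 to 69.1 and 56.4 CPM, with 206 in S4. Of 14 heat shock genes 12 fell, 1 rose and 1 did not pass (12 and 1 adjusted over the list alone; list p = 0.00012, adjusted p = 0.372 with an estimated correlation). The chaperone gene HSPA8 fell by 0.87 ± 0.08. Of 19 pentose phosphate genes and NRF2 targets 12 fell, 2 rose and 5 did not pass (13 and 3 adjusted over the list alone; list p = 0.000969, adjusted p = 0.346 with an estimated correlation). AKR1C2, a ketosteroid reductase, fell by 0.99 ± 0.10. The matrix list had 12 of 21 down, 2 up and 7 not passing (12 and 2 adjusted over the list alone; list p = 0.0103, adjusted p = 0.372 with an estimated correlation). The metalloprotease gene MMP7 fell by 1.99 ± 0.14. The integrin and adhesion list had 10 of 22 down, 2 up and 10 not passing (11 and 2 adjusted over the list alone; list p = 0.0103, adjusted p = 0.372 with an estimated correlation). LAMB3, of the basement membrane, fell by 2.52 ± 0.14.

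**Figure D3:**
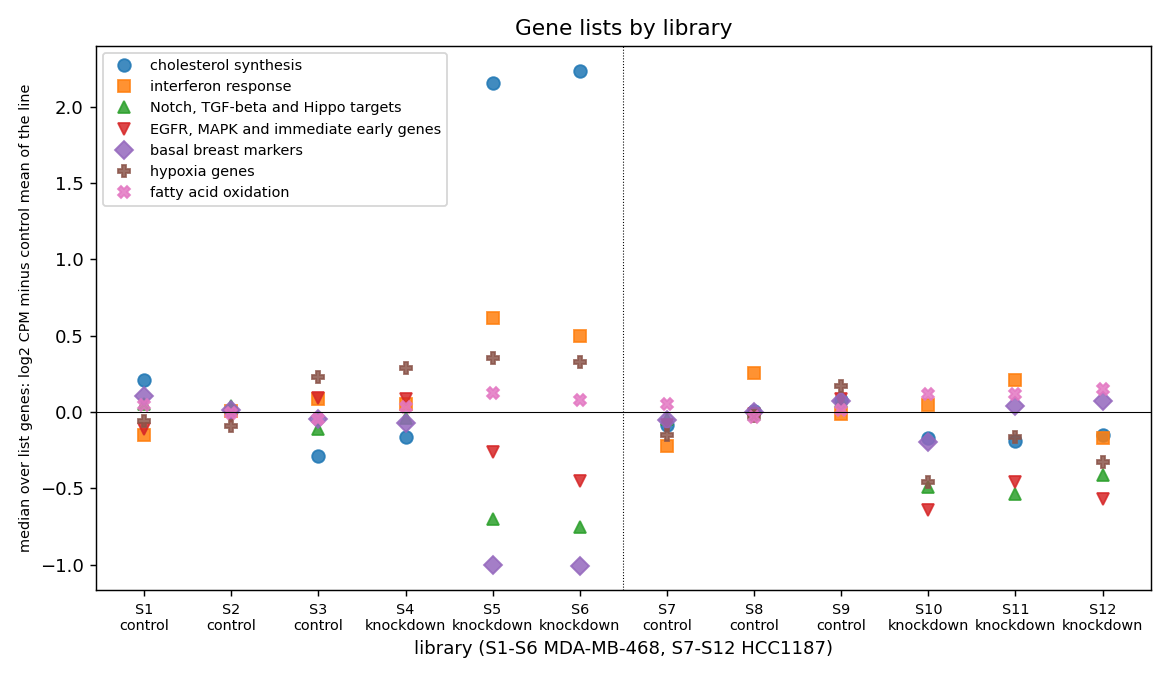
Median log2 CPM of 7 gene lists in each library, minus the mean of the controls of its line; the lists were picked for display after their values were seen. The cholesterol synthesis list stands at −0.16 in S4 and at 2.16 and 2.24 in S5 and S6.

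For the other lists of that fit, the EGFR, MAPK and immediate-early list had 12 of 24 genes down, 5 up and 7 not passing (13 and 5 adjusted over the list alone; list p = 0.00508, adjusted p = 0.471 with an estimated correlation). NF-kB and cytokine genes had 8 of 19 down, 1 up and 10 not passing (8 and 2 adjusted over the list alone; list p = 0.0103, adjusted p = 0.377 with an estimated correlation), and S phase genes 8 of 26 down, 2 up and 16 not passing (9 and 2 adjusted over the list alone; list p = 0.0296, adjusted p = 0.665 with an estimated correlation). The TCA cycle had 10 of 22 up, 1 down and 11 not passing (10 and 2 adjusted over the list alone; list p = 0.00918, adjusted p = 0.372 with an estimated correlation). In all, 16 of 39 lists shifted without S4 (6 up, 10 down) and 20 with all 6 libraries (11 up, 9 down), 0 of either with an estimated correlation. Of the 16, those of the S phase (fry adjusted p = 0.196) and of mitochondrially encoded genes (0.104) did not pass with fry. The fit without S4 called 40.7% of all genes tested, which is the background for its counts of list members. With 6 libraries the lists of glycolysis (adjusted p = 0.00369), hypoxia (0.00746) and interferon genes (0.00269) were up and those of basal markers (0.00952), the G2/M phase (0.0017) and the S phase (0.00369) down, with 0 single genes of any of them called. Control S3 lies near the knockdown libraries in some of these: its list median is 0.23 for hypoxia (0.29 to 0.36 in S4 to S6), −0.14 for the S phase (−0.20 to −0.16) and −0.14 for G2/M (−0.22 to −0.18).

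The response to knockdown differed between the lines for 613 of 16328 genes, 411 with the higher change in MDA-MB-468 and 202 with the higher change in HCC1187. The spread of a gene was estimated over both lines together here, although the MDA-MB-468 libraries vary more. CYFIP1, a regulator of actin branching, differed most clearly, by 1.78 ± 0.16 on the log2 scale (adjusted p = 9.72e-05, n = 3 per group): it fell in HCC1187 (−1.41) and had 0.38 in MDA-MB-468 (adjusted p = 0.208). KIF1C (1.197 ± 0.12), EXTL3 (1.54 ± 0.16), the sodium pump subunit ATP1B1 (1.34 ± 0.14), AHNAK (1.25 ± 0.14) and MORF4L1 (1.54 ± 0.17) also had the higher change in MDA-MB-468, and each fell in HCC1187. PTBP2, a neural splicing regulator, rose in HCC1187 (1.06) and had −0.41 in MDA-MB-468, a difference of −1.48 ± 0.19. BEST1 (−4.03 ± 0.57), VCP (−0.84 ± 0.12), CDKN3 (−0.94 ± 0.14) and C22orf46 (−1.19 ± 0.18) differed in the same direction. The difference for SOX9-AS1 itself, 0.77 ± 0.38, did not pass (adjusted p = 0.268). The count is 4300 without S4 and 173 without S1, 129 without S2, 358 without S3, 164 without S5, 238 without S6, 304 without S7, 177 without S8, 152 without S9, 178 without S10, 301 without S11 and 256 without S12.

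A test of the lists for a difference between the lines was chosen after the data were seen. With 12 libraries the cholesterol synthesis genes had the higher change in MDA-MB-468 (list p = 9.03e-06, adjusted p = 0.592 with an estimated correlation), and so did those of hypoxia (list p = 1.31e-05, adjusted p = 0.445 with an estimated correlation) and glycolysis (list p = 7.55e-05, adjusted p = 0.445 with an estimated correlation). Without S4 the cholesterol list had list p = 3.1e-23 (adjusted p = 0.124 with an estimated correlation) and the fatty acid synthesis list had list p = 1.14e-06 (adjusted p = 0.0235 with an estimated correlation).

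With all 6 libraries of MDA-MB-468, 0 genes changed in the same direction in both lines in edgeR, since only BEST1 passed there and it had 0.29 in HCC1187 (adjusted p = 0.64). At unadjusted p under 0.05 there were 2554 genes of MDA-MB-468 and 5304 of HCC1187, and DESeq2 shared 51 genes (24 up, 27 down), limma-voom 0 and edgeR with no filter on low counts 194 (71 up, 123 down). Without S4 the shared genes number 718. CCN2 is the largest shared fall among them by the smaller of its changes, with −3.66 in MDA-MB-468 without S4 and −2.24 in HCC1187, followed by HMOX1 (−1.23 and −1.16), THBS1, the matrix protein thrombospondin (−3.99 and −1.16), ID4 (−1.07 and −1.17), GPRC5A (−1.52 and −1.02) and DPP4 (−1.51 and −0.99). Among genes that the naming rule allows, the largest shared rises were TXLNB (2.22 and 1.79), SNAI3-AS1 (2.94 and 1.18), AKAP6 (2.15 and 1.15), GMDS-DT (1.05 and 1.19), CCT6B (1.03 and 1.24) and CARF (1.01 and 1.25). Of the 718, 295 rose in both lines against 244.5 expected (exact hypergeometric test, p = 0.000115) and 423 fell in both against 365.5 expected (p = 0.000181 by the same test), of 12421 genes tested in both. Genes of opposite direction were fewer than the expected numbers, 334 against 343.9 and 185 against 259.9. Across 12267 genes the log2 fold changes of the lines correlated with r = 0.118 with 6 libraries, and across 12421 genes with r = 0.088 without S4. The hypergeometric test treats genes as independent replicates, which they are not. The rise of CCT6B in HCC1187 is lost without S7 (adjusted p = 0.089) or S12 (0.124), with DESeq2 (0.0539) and with all 12 libraries fitted together (0.105). That last fit also loses the HCC1187 changes of THBS1 (adjusted p = 0.61), AKAP6 (0.19), SNAI3-AS1 (0.0896) and DPP4 (0.069).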

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

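The splits of the libraries in this part were fixed before the data were examined, while the tests on library S4 (its depth and its levels of BEST1, SOX9 and SOX9-AS1) were all chosen only after the result was seen. The response to knockdown differed between the lines for 613 genes, 36 of them named here. The differences (MDA-MB-468 minus HCC1187, log2 scale) with the higher change in MDA-MB-468 were INSIG1 3.92, SCD 3.64, STAC2 3.61, PNPLA3 3.60, DDIT4 3.32, FOS 2.67, SQLE 2.50, MVD 2.44, HMGCS1 2.33, H1-2 1.90, CYFIP1 1.78, TMEM263 1.76, MORF4L1 1.54, EXTL3 1.54, SCD5 1.36, ATP1B1 1.34, AHNAK 1.25, KIF1C 1.197, TAF13 1.18, P4HA1 1.12, LDHA 1.107, NDRG1 1.05, DUSP1 1.05, GAS5 0.95 and RAC1 0.48. Those with the higher change in HCC1187 were BEST1 −4.03, THBS4 −2.51, FAM86C2P −1.65, PTBP2 −1.48, WDR31 −1.46, C22orf46 −1.19, CDKN3 −0.94, VCP −0.84, CPT2 −0.81, ERAP1 −0.71 and ECHS1 −0.66. Adjusted p ran from 9.72e-05 for CYFIP1 to 0.0498 for RAC1. This fit shares the spread of each gene between the lines. The biological coefficient of variation was 0.161 in MDA-MB-468 and 0.081 in HCC1187, so these p-values can understate the spread among the MDA-MB-468 libraries. Of the genes listed here, only BEST1 passed in MDA-MB-468 fitted by itself with all 6 libraries.

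Of 100 drawn splits 3, the real one included, gave as many as 613 differing genes. The highest other gave 1670; it keeps the real groups and swaps the labels of HCC1187, so it tests the sum of the responses of the lines. Another split, which sets S4 with S2 and S3 and also swaps the labels of HCC1187, gave 1167, against 573 without the swap. The structure of the samples that these counts point to is the grouping of HCC1187, since these splits keep S7, S8 and S9 together and no drawn split that parts them gave more than 1. For the shared genes 100 of 100 splits reached the real number of 0 (highest other 0), so this count carries no information. For single genes 1 of 10 splits was as large as the real one in MDA-MB-468 (real 1, highest other 0) and 1 of 10 in HCC1187 (real 3418, highest other 0), and for lists 1 of 10 in each (real 20, highest other 16; real 17, highest other 15); 10 splits are too few for a share under 0.05.

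Across 12724 genes S4 correlated more closely with the controls of MDA-MB-468 (r = 0.9838 to 0.9931) than with S5 (0.9573) and S6 (0.9508). Control S3 was closer to S4 (0.9931) than to the controls S1 (0.9883) and S2 (0.9907). A control library under a knockdown label would explain why S4 lies with the controls. BEST1 has an upper bound of 1.68 CPM in S4, below the controls (7.05 to 7.71). However, it was the only gene of 13638 to pass with S4 counted as knockdown, so a low value there follows from how it was picked. It is also 1 gene, which overlaps FTH1, so it cannot decide the label. SOX9, which was always named, stood at 136 CPM in S4 (128 to 145, counting error only). That is below the controls (164 to 210) and above S5 (109) and S6 (99.3). SOX9 is a single gene as well and overlaps SOX9-AS1 on the opposite strand, so a mislabelled control stays open. Shallow sequencing is argued against by a ratio of 0.956 between the depths of S4 and S6. A weaker knockdown in S4 could also give this and stays open: SOX9-AS1 there is 5.04 CPM (3.51 to 7.01), an interval that holds the control mean of 6.06 as well as S5 (4.54) and S6 (4.96).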

How the results depend on the processing

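Leaving libraries out and changing tools moved the counts as follows, and no fold change of a named gene was reversed. In MDA-MB-468 the 1 gene became 1441 with no filter, 289 with DESeq2, 0 with limma-voom, 887 with all 12 libraries together, 0 at p under 0.01, and 0 to 5676 with a library left out, the highest without S4. With S4 left out, alternatives added after the data were seen gave 4381 genes with DESeq2, 5609 with limma-voom and 1284 at an absolute log2 fold change of 1. SOX9-AS1 ranged from −0.37 to −0.23 there. Its 20 shifted lists became 0 with an estimated correlation, 0 with fry and 15 to 18 with a library left out; without S4, 0 with an estimated correlation and 20 with fry (8 up, 12 down), the latter added after the data were seen. In HCC1187 the 3418 genes became 1499 with all 12 libraries together, 327 at an absolute log2 fold change of 1, 1839 at p under 0.01 and 2213 to 3410 with a library left out. With library totals as the only scaling the balance turned, to 2104 up and 1545 down from 1464 up and 1954 down. SOX9-AS1 ranged from −1.28 to −0.87 there and had no adjusted p in DESeq2. The count of 17 lists became 0 with an estimated correlation, 11 with fry and 11 to 19 with a library left out. The 11 of fry are not all among the 17. Luminal breast markers (fry adjusted p = 0.000157), fatty acid synthesis (0.0234) and epithelial genes (0.0259) passed with fry only. Glycolysis, hypoxia and cholesterol synthesis (0.0891 each) did not pass with fry. Nor did the histone (0.0816), matrix, ATF4, integrin, ribosomal and short-lived RNA lists. The 613 differing genes became 1415 with no filter, 1142 with DESeq2 and 129 to 4300 with a library left out. The 0 shared genes became 194 with no filter, 51 with DESeq2 and 0 to 718 with a library left out. Of 598 values of named genes other than SOX9-AS1 in HCC1187 17 were weaker, and SOX9-AS1 was weaker without S7, S9, S11 or S12; of 556 in MDA-MB-468 113 were stronger and 6 weaker, the 6 all of BEST1. A stricter threshold lowers a count by construction; for the other shifts the cause was not tested. No paired analysis was possible because the columns carry no replicate number, and the alternatives with a replicate block were not run. With 6026376 lane 1 counts in the shallowest library, genes of a few reads such as SOX9-AS1 in HCC1187 are the ones limited by using 1 of 3 lanes.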

Other observations

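Small RNAs that the rule for named genes leaves out are given here, chosen after their values were seen. RN7SL1, the RNA of the signal recognition particle, rose in HCC1187 from 13.8 ± 4.78 to 208 ± 81.4 CPM (log2 fold change 3.93 ± 0.22, adjusted p = 7.1e-11, n = 3 per group), RN7SL3 by 3.89 ± 0.36, and SNORD3A from 0.377 to 12.4 CPM (5.01 ± 0.37, adjusted p = 4.62e-09). In MDA-MB-468 RN7SL1 averaged 5.37 CPM in the controls and stood at 15.9 CPM in S4, 76.6 in S5 and 81.1 in S6 (log2 fold change 3.395 ± 0.69, adjusted p = 0.205 with all 6 libraries; 3.81, adjusted p = 1.22e-07 without S4). In HCC1187 the summed mitochondrial rRNA had a knockdown to control ratio of 1.322 and the snRNAs 1.103, both with overlapping libraries, while the histone genes had a median log2 fold change of −0.75. How the RNA was selected was not tested as a source of these values. Of 1488 long non-coding RNA genes tested in HCC1187 214 rose and 58 fell, against 1198 and 1874 of 12889 protein-coding genes.

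In this part the sums of non-coding classes, the thinning of libraries, the word search in the shared fallen genes and its length-matched sets were written before their results were seen. The exact definition of the summed classes, the strata by GC content, the revised reading of that word search, and every word test in HCC1187 and in MDA-MB-468 alone were chosen only after the result was seen.

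Long non-coding and other genes of little mRNA made up more of the rises than of the falls in HCC1187. Depth is argued against: with every library thinned to 6026376 counts 1251 genes still rose, of 1464, and 141 long non-coding RNA genes, of 214. A larger share of nuclear or unspliced RNA in the knockdown libraries might also give this; the summed non-coding classes have a knockdown to control ratio of 0.91 with long non-coding RNAs and 1.115 without them, every knockdown library being above every control in the latter. The first ratio meets the bound written against this explanation (under 1.1), but most of that sum is long non-coding RNA (37259.9 CPM in S7 against 7040.8 without it), which is not silent in mRNA. The other, 1.115, lies between that bound and the 1.2 set for the cause. Without the class of RN7SL1 (misc_RNA, 39.2 to 257 CPM) it falls to 1.083, which is under 1.1 as well, with every knockdown library still above every control. The unconfirmed genes (biotype TEC), at 567 CPM in the controls and 484 in the knockdown, and the short-lived and intron-rich nuclear RNAs, with a median of −0.23, go against the explanation. Transcribed processed pseudogenes (332 to 404 CPM), transcribed unitary pseudogenes (575 to 697) and snoRNAs (45.5 to 55.5) go with it. In each of these classes every knockdown library lies above every control. The explanation stays open beside a response of the genes themselves.

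Genes that fell might have been hit through their 3′ UTRs by an shRNA seed rather than through SOX9-AS1. In the shared fallen genes the lowest Bonferroni p by length strata was 0.000347 (TTTAAAG, in 242 of 414 genes against 194.1 expected), so the threshold written beforehand was met. Of 1000 length-matched sets 0 were as high (58.45% against at most 53.86%). That word was picked for its excess in these same genes, so the matched sets add no support beyond the Bonferroni p. With strata by length and GC the same word had 0.214 and another, GCGTTGC, had 0.00678, against 13 words past the threshold by length alone, so base composition argues against a seed for TTTAAAG. In HCC1187 genes with CCGTAAA differed from other genes by −0.217 in log2 fold change (95% interval −0.256 to −0.179, 233 genes, Bonferroni-adjusted p = 1.74e-24), rank 1 of 15838 words, and TCCGTAA, ATGCCTT and ATGCCTA had ranks 2, 3 and 10. Fallen genes held CCGTAAA in 117 of 1692 cases against 55.4 expected (6.91% against at most 3.31% in matched sets; Bonferroni-adjusted p = 1.31e-19 by length and 4.36e-19 by length and GC, where 16 words pass against 1710). CCGTAAA was picked from the HCC1187 fold changes, so the fallen genes and their matched sets are not a separate test of it.

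In MDA-MB-468 CCGTAAA had −0.012 without S4 (95% interval −0.082 to 0.058) and −0.002 in S4, so its genes did not fall there. SOX9-AS1 had no passing fall in that line either. A weakly active shRNA could give both, so these values cannot decide on a seed shared by the lines. The genes that fell in both lines held CCGTAAA in 27 cases against 13.8 expected by length. That excess did not pass when adjusted over all 15838 words, a strict bar for 1 word carried over from HCC1187. It therefore does not show that an excess is absent. Those genes were also picked partly by their fall in HCC1187, so an excess there would not be separate support. TCCGTAA lies in GAGGCATGGTATCCGTAAC, CCGTAAA matches 6 of its bases in a row, and ATGCCTT and ATGCCTA match 6 on its other strand. This site is in exon 4 of 7 of the longest SOX9-AS1 transcript (chromosome 17, 72084000 to 72084018, minus strand, GRCh38), present in 7 of 19 transcripts. Only 3 of 58721 genes hold the paired words, a pattern built after the search, and 239 words pass in HCC1187, many rich in A and T. The search covered 3 sets of fold changes and 2 gene sets, each of the latter under 2 stratifications. The shRNA sequence is not given in the sources used here, so a seed effect in HCC1187 could be real and stays a hypothesis beside an effect of SOX9-AS1 itself.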
